A study of Sus scrofa with 12 samples.

How the data were processed

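The study measured RNA levels in pig cells on the Affymetrix porcine genome array, a short-oligonucleotide array on which each transcript is read by a probe set, a group of short probes whose brightness is summarised to 1 value. There were 12 arrays in 4 groups of 3, and the labels call the arrays of a group biological replicates. Per the labels' protocols, RNA was extracted with Trizol and purified on RNeasy columns, and biotin-labelled RNA was made from 5 µg of total RNA by amplification from the 3′ end. The labels do not say which animals or cultures the replicates came from, so the p-values measure the spread between these samples, part of which may be technical.

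The deposited values are log2 expression values, which the authors made by robust multi-array averaging (RMA) per the submitters' processing notes. RMA corrects the background, sets all arrays to a common distribution and summarises each probe set. Its software version and settings were not given in the sources used here. The values were used as deposited. They hold no detection calls, so a low level cannot be told from background here, and changes of genes near the floor are understated. The number of arrays limits the precision. Setting arrays to a common distribution also removes any difference in total RNA per cell, so every change is relative to the other RNA on the array.

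The table held 24123 probe sets. The 124 Affymetrix control probe sets were left out of the tests, which leaves 23999. Gene names came from the platform annotation supplied with the data, which can be old. Of the tested probe sets, 10069 had 1 gene symbol, 198 had several and 13732 had none here, and none was named from a probe set with several symbols. The named probe sets stood for 6765 genes. For the 2261 genes with several probe sets, the probe set with the highest mean level represented the gene. In naming genes, 359 placeholder symbols were skipped. No genome coordinates are given, because the build behind the array was not given in the sources used here.

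All computation from the deposited values was done in R 4.3.3 with limma 3.58.1, and the figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A linear model with 1 mean per group was fitted to each probe set over all groups, so that the groups share 1 estimate of the spread. Contrasts were tested with limma's moderated, two-sided test. P-values were adjusted by the Benjamini-Hochberg method over all 23999 probe sets, and an adjusted p under 0.05 counted as changed, or as rose or fell. The contrasts were DFAT minus MA, DFOG minus GC, the difference between these 2 changes (called the interaction), MA minus GC and DFAT minus DFOG. An F-test compared the 4 groups together. The design planned 12 separate samples, but DFOG replicates 2 and 3 were nearly identical and their mean was used as 1 sample, so that the fit rests on 11 samples and 7 residual degrees of freedom, with DFOG at n = 2 and the other groups at n = 3. Log2 changes are given with their standard error from the fit, and levels as mean ± SD over samples on the log2 scale.

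The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. In each of the 2 dedifferentiation comparisons, the named genes were the 10 with the largest rise and the 10 with the largest fall among genes past the test whose groups do not overlap, plus up to 4 members of each list with the largest change past the test, or 8 for the adipocyte and granulosa identity lists. For the other 3 contrasts they were the 6 largest in each direction. For changes in both dedifferentiations they were the 8 per direction with the largest smaller change, and for opposite changes up to 6 per direction. Values of other list members are also given as examples.

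The 27 gene lists covered adipocyte identity, fatty acid and triglyceride synthesis, lipolysis and fatty acid oxidation, granulosa cell identity, steroid hormone synthesis, cholesterol synthesis, mitosis, DNA replication, fibrillar matrix, basement membrane, matrix proteolysis, actin cytoskeleton and adhesion, mesenchymal stromal cell surface, pluripotency, osteogenic, chondrogenic and myogenic lineages, cytosolic ribosome, oxidative phosphorylation, glycolysis and hypoxia response, immediate early and heat shock genes, and cytokines and chemokines. The remaining ones held markers of other cells that a preparation could contain, namely macrophages, lymphocytes, endothelial cells, erythrocytes, theca cells and oocytes, epithelial and mesothelial cells, and skeletal muscle. Each list was tested with limma's camera, which asks whether its members changed more in one direction than the other genes. The correlation between genes was preset at 0.01, and p-values were adjusted over 135 list tests. Camera with a correlation estimated from these samples was run beside it. With the preset correlation 46 of the 135 list tests passed, and with the estimated correlation none did, the lowest adjusted p being 0.0610. A further 12 lists were chosen after these results had been seen and were adjusted over their own 60 tests.

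The alternatives were a filter that left out the dimmest 1 of 3 probe sets (mean level under 5.27), quantile normalization applied again, centring of each array on its median or on 8 reference genes, limma with a trended and robust prior, array weights, a fit on the arrays of the comparison alone, a replicate block, a 2-fold minimum, the mean over a gene's probe sets, the limma test fry, which asks whether a list's genes moved on balance one way and does not compare them with other genes, and each array left out in turn. Chosen after the data were seen were the 12 arrays as separate samples, the difference between the actin 3′ and 5′ control probe sets as a covariate, and centring on the poly-A controls, bacterial transcripts that can be added to a sample before labelling. It is not stated whether equal amounts of these were added, so the values with this centring may reflect the amounts added and not the cells. Differences in control probe sets between groups were tested with exact permutation tests, two-sided. For 3 against 3 samples the smallest p such a test can give is 0.1.

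The fit was tested on simulated data with the size of the real table, 23999 probe sets, of which 200 were changed per comparison. For DFAT against MA it recovered 0 of 67 changes of 0.5 on the log2 scale, 38 of 67 (56.7%) of 1 and 58 of 66 (87.9%) of 2, with 5 wrong calls among 23799 unchanged probe sets. For DFOG against GC it recovered 0 of 67 at 0.5, 22 of 67 (32.8%) at 1 and 58 of 66 (87.9%) at 2, with 1 wrong call. Far fewer probe sets were changed here than were called in the data (7706 and 5971), which makes the Benjamini-Hochberg threshold stricter. These shares therefore do not measure the recovery in the real comparisons. In the simulated DFAT and MA values camera called the shifted list of 20 genes, and 3 of 100 unchanged lists had an unadjusted p under 0.05. Because these genes were simulated, the check cannot tell whether the preset or the estimated correlation suits the real genes. It therefore does not settle the list tests, whose outcome differed between these 2 correlations.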

Results

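RNA levels were measured in 2 kinds of pig cells before and after they had lost their specialised state in culture. Mature adipocytes (MA) are the lipid-filled cells of fat tissue. Dedifferentiated fat cells (DFAT) were obtained from them by ceiling culture, in which floating fat cells attach to the upper surface of a filled flask, and were grown to semiconfluence. Granulosa cells (GC) line the ovarian follicle and surround the oocyte, and dedifferentiated granulosa cells (DFOG) were grown from them in vitro to semiconfluence. The study set out to find the genes and functions that go up or down as each cell type dedifferentiates. Both comparisons set isolated cells against cells grown in culture, so dedifferentiation cannot be told apart from other effects of culture. The group medians over all tested probe sets lay between 6.39 ± 0.03 (SD, n = 3) in MA and 6.47 ± 0.02 (SD, n = 3) in GC on the log2 scale.

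DFOG replicates 2 and 3 differed by less than any other pair of arrays of a group. The SD of their differences over all tested probe sets was 0.07 on the log2 scale, against 0.31 to 0.62 in the 11 other pairs, and 10.4% of probe sets differed by more than 0.1. They were counted as 1 sample, the mean of both, so DFOG has n = 2.

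Control probe sets were compared between groups, and none of the 8 tests passed after adjustment. The tests of MA against GC, with 3 against 3 samples, could not pass, and counting them makes the adjustment of the others stricter. The lack of a passing test therefore does not show that RNA quality was alike in isolated and cultured cells. The 3′ minus 5′ difference of the actin control, which becomes larger when RNA is shorter or less fully copied, was 1.88 ± 0.52 (SD, n = 3) in MA and 1.35 ± 0.55 (SD, n = 3) in GC, and 0.61 ± 0.33 (SD, n = 3) in DFAT and 0.39 ± 0.33 (SD, n = 2) in DFOG. The isolated cells lay 1.09 above the cultured cells in an exact permutation test over 462 arrangements of 6 against 5 samples (p = 0.00649, adjusted p = 0.0519 over 8 tests of controls). The same difference for the GAPDH control was 0.40 (exact p = 0.0801, adjusted p = 0.2). That of the hybridisation controls was 0.21 (exact p = 0.0996, adjusted p = 0.2), and that of the poly-A controls was -0.07 (exact p = 0.855, adjusted p = 0.855). The poly-A controls averaged 8.29 ± 0.18 (SD, n = 3) in MA, 6.95 ± 0.30 (SD, n = 3) in GC, 7.66 ± 0.43 (SD, n = 3) in DFAT and 7.74 ± 0.02 (SD, n = 2) in DFOG, and the 1.35 between MA and GC had an exact p of 0.1, the smallest that 3 against 3 samples allow. The IRP controls were not tested. The IRP 3′ control lay at 8.50 in DFAT 2 and 5.48 in DFAT 3, against 2.71 to 3.06 on the other arrays, and the reason is not known.

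**Figure D1:**
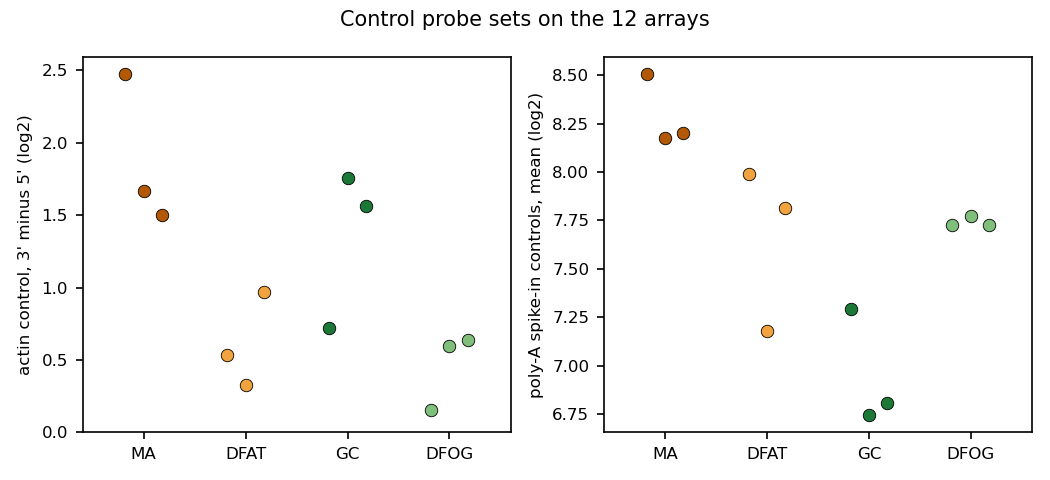
Control probe sets on each array, by group. Points are the 12 arrays, on log2 scales; with DFOG replicates 2 and 3 averaged first, the actin 3′ minus 5′ difference averaged 1.88 in MA and 1.35 in GC against 0.61 in DFAT and 0.39 in DFOG, and the poly-A controls averaged 8.29 in MA and 6.95 in GC.

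Dedifferentiation of mature adipocytes was examined by comparing DFAT with MA (n = 3 each). In the adipocyte identity list 10 of 14 members fell, while 17 of 21 actin cytoskeleton and adhesion genes, 14 of 20 fibrillar matrix genes and 12 of 14 mitosis genes rose. ADIPOQ, the adipocyte hormone adiponectin, fell from 13.99 ± 0.28 to 5.78 ± 0.94 (SD), a log2 change of -8.21 ± 0.37 (SE, limma adjusted p = 5.52e-08). LIPE, the hormone-sensitive lipase that breaks down stored fat, changed by -6.34 ± 0.24 (SE, limma adjusted p = 1.51e-08). ACTG2, a smooth muscle actin, rose from 4.31 ± 0.12 to 14.31 ± 0.06 (SD), with an SE of 0.15 on the change (limma adjusted p = 2.41e-11). Of the 23999 probe sets, 7706 changed, 3765 up and 3941 down, and 4781 of them changed at least 2-fold. With the actin 3′ to 5′ difference as a covariate 4301 of the 7706 kept their call. Among the 6765 named genes, 1404 rose and 1380 fell.

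The largest falls beside ADIPOQ were those of CA3, a carbonic anhydrase abundant in fat (-8.67 ± 0.24), PON3, a lactonase (-8.62 ± 0.33), CDO1, a cysteine-degrading enzyme (-7.64), SGK2 (-7.32), PDK4, an inhibitor of pyruvate dehydrogenase (-7.25), ENPP2 or autotaxin (-6.76), TSPAN13 (-6.62), ITIH5 (-6.55) and PDE6C (-6.37). The adipocyte identity list had 10 of 14 measured members fall and none rise (10 fell when adjusted over the list alone). Its median log2 change was -4.37 (camera adjusted p = 5.88e-07, and adjusted p = 0.0610 with an estimated correlation). Examples are the glycerol-3-phosphate dehydrogenase GPD1 (-5.66), lipoprotein lipase LPL (-5.42), the retinol carrier RBP4 (-5.34), CIDEA (-5.06), the fat cell master regulators PPARG (-4.51) and CEBPA (-4.36), and FABP4 (-4.38), which went from 14.06 ± 0.09 to 9.68 ± 0.79 (SD). In fatty acid and triglyceride synthesis 12 of 17 members fell and 2 rose, with the same counts adjusted over the list alone, and the median was -1.89 (camera adjusted p = 0.000102, and adjusted p = 0.287 with an estimated correlation). DGAT2, which adds the last fatty acid of a triglyceride, changed by -5.90, pyruvate carboxylase PC by -5.21, ELOVL6 by -4.83 and fatty acid synthase FASN by -4.40, while the desaturases FADS1 and FADS2 rose by 3.48 and 2.14. In lipolysis and fatty acid oxidation 15 of 18 members fell and 1 rose, again with the same counts adjusted over the list alone (median -1.46, camera adjusted p = 2.92e-06, and adjusted p = 0.0610 with an estimated correlation). ACAA2, a thiolase of beta-oxidation, changed by -3.63, and the member that rose was CPT1A (2.81), the carnitine palmitoyltransferase found in liver and many other tissues.

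In the actin cytoskeleton and adhesion list 17 of 21 members rose and none fell (18 rose when adjusted over the list alone), with a median of 2.41 (camera adjusted p = 1.70e-10, and adjusted p = 0.194 with an estimated correlation). They included calponin CNN1 (7.93 ± 0.25), smooth muscle actin ACTA2 (7.07 ± 0.24), tropomyosin TPM2 (6.85 ± 0.26) and the fibronectin receptor subunit ITGA5 (5.84). Among the largest rises outside the list were TMEM158 (7.86 ± 0.48), the LIM-domain protein FHL2 (7.50 ± 0.21), the mesenchymal cadherin CDH11 (7.41 ± 0.21) and RAI14 (6.90 ± 0.17). The fibrillar matrix list had 14 of 20 members rise and none fall, also when adjusted over the list alone (median 2.65, camera adjusted p = 1.70e-06, and adjusted p = 0.306 with an estimated correlation). Tenascin TNC rose by 6.98 ± 0.37, biglycan BGN by 5.12, fibronectin FN1 by 4.38 and the collagen COL1A2 by 4.08. Of the mesenchymal stromal cell surface list 6 of 12 members rose and 1 fell (7 and 1 when adjusted over the list alone; median 1.46, camera adjusted p = 0.0188, and adjusted p = 0.533 with an estimated correlation), among them THY1 (4.24) and PDGFRB (3.39), with CD9 at -2.70. The actin 3′ minus 5′ difference was 1.88 in MA and 0.61 in DFAT.

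Cell cycle genes were low in MA and higher in DFAT. In mitosis 12 of 14 members rose and none fell (14 rose when adjusted over the list alone; median 2.51, camera adjusted p = 1.26e-05, and adjusted p = 0.535 with an estimated correlation). Cyclin CCNB1 went from 4.48 ± 0.30 to 9.79 ± 1.26 (SD) and topoisomerase TOP2A from 4.13 ± 0.27 to 8.82 ± 1.14. In DNA replication 9 of 13 rose and none fell (10 when adjusted over the list alone; median 1.20, camera adjusted p = 0.00157, and adjusted p = 0.591 with an estimated correlation), led by the nucleotide synthesis genes RRM2 (5.02) and TYMS (4.44). Glycolysis and hypoxia response had 11 of 16 members rise and 2 fall (12 and 2 when adjusted over the list alone; median 1.10, camera adjusted p = 0.0131, and adjusted p = 0.690 with an estimated correlation). Lactate dehydrogenase LDHA rose by 3.24 and the glucose transporter SLC2A1 by 2.41. In oxidative phosphorylation 7 of 16 fell and none rose (8 fell when adjusted over the list alone), COX7A1 by -2.98, and the median was -0.39, or 0.24 with arrays centred on the poly-A controls. Its camera adjusted p was 0.0299 (adjusted p = 0.672 with an estimated correlation).

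Immediate early and heat shock genes had 9 of 14 members fall and 3 rise (10 and 3 when adjusted over the list alone; median -2.05, camera adjusted p = 0.00685, and adjusted p = 0.555 with an estimated correlation). FOS changed by -5.07, BTG2 by -3.97 and ZFP36 by -3.35, while the members that rose were the chaperones HSPA8 (1.80), HSPH1 (0.71) and HSP90AA1 (0.48). Markers of macrophages had 8 of 13 members fall and none rise, also when adjusted over the list alone (median -1.04, camera adjusted p = 0.00247, and adjusted p = 0.533 with an estimated correlation). The complement gene C1QC changed by -3.59 ± 0.73, the MHC class II chain CD74 by -3.24 ± 0.22, LAPTM5 by -2.48 and CD163 by -1.95.

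The remaining lists did not pass camera in this comparison. Cholesterol synthesis had 5 of 10 members rise and 1 fall (adjusted p = 0.195), with SQLE at 3.51. Matrix proteolysis had 6 of 15 rise and 1 fall (adjusted p = 0.0803), with the protease inhibitor TIMP1 at 5.73 and the plasminogen activator PLAU at 4.56. Cytokines and chemokines had 7 of 16 rise and 2 fall (adjusted p = 0.167), with IL18 at 3.68 and IL15 at -3.74. Osteogenic, chondrogenic and myogenic genes had 3 of 15 rise (adjusted p = 0.452), SPP1 or osteopontin by 5.71 and desmin DES by 3.86 among them. The pluripotency list had 3 of 5 measured members fall, by -1.86 for KLF4 (adjusted p = 0.166), and POU5F1 did not pass the test (-0.28). The granulosa identity list had 4 of 22 rise and 3 fall (adjusted p = 0.344), those that rose being the protease inhibitor SERPINE2 (6.57), versican VCAN (6.75), the gap junction gene GJA1 (4.33) and BMPR1B (3.91). In steroid hormone synthesis 4 of 15 fell (adjusted p = 0.265), HSD3B1 by -4.27. In basement membrane 1 of 6 fell, SPARCL1 by -4.87 (adjusted p = 0.934), and the list's median was 0.33 while its mean was -0.60. In cytosolic ribosome 4 of 18 rose (adjusted p = 0.385). Of the other marker lists, endothelial cells had 4 of 12 fall and 1 rise (adjusted p = 0.179), lymphocytes 2 of 10 fall (adjusted p = 0.208), erythrocytes 1 of 5 fall (adjusted p = 0.704), theca cells and oocytes 2 of 9 fall (adjusted p = 0.208), epithelial and mesothelial cells 2 of 9 fall (adjusted p = 0.226), CLDN4 by -3.10 among them, and skeletal muscle 2 of 10 fall (adjusted p = 0.478). Adjusted over the list alone, the counts of the lists in this paragraph were the same, except that cytokines had 8 rise and 3 fall and no lymphocyte or erythrocyte marker passed. With arrays centred on the poly-A controls, 6884 probe sets were higher and 1340 lower in DFAT, against 3765 and 3941, since that centring moved the median of all probe sets from -0.07 to 0.56. Matrix proteolysis passed with array weights (adjusted p = 0.0379) and without MA replicate 1 or DFAT replicate 1 (adjusted p = 0.0450 and 0.0155). The test fry, which asks whether a list moved on balance one way and not whether it moved more than other genes, passed for 12 of these lists. Camera no longer passed for glycolysis without DFAT replicate 2 (adjusted p = 0.0523), with the actin covariate (adjusted p = 0.0747) or with poly-A centring (adjusted p = 0.0610), nor for oxidative phosphorylation without DFAT replicate 2 or 3 (adjusted p = 0.0519 and 0.0641), with quantile normalization again (adjusted p = 0.0583), with poly-A centring (adjusted p = 0.115) or with the mean over a gene's probe sets (adjusted p = 0.178).

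**Figure D2:**
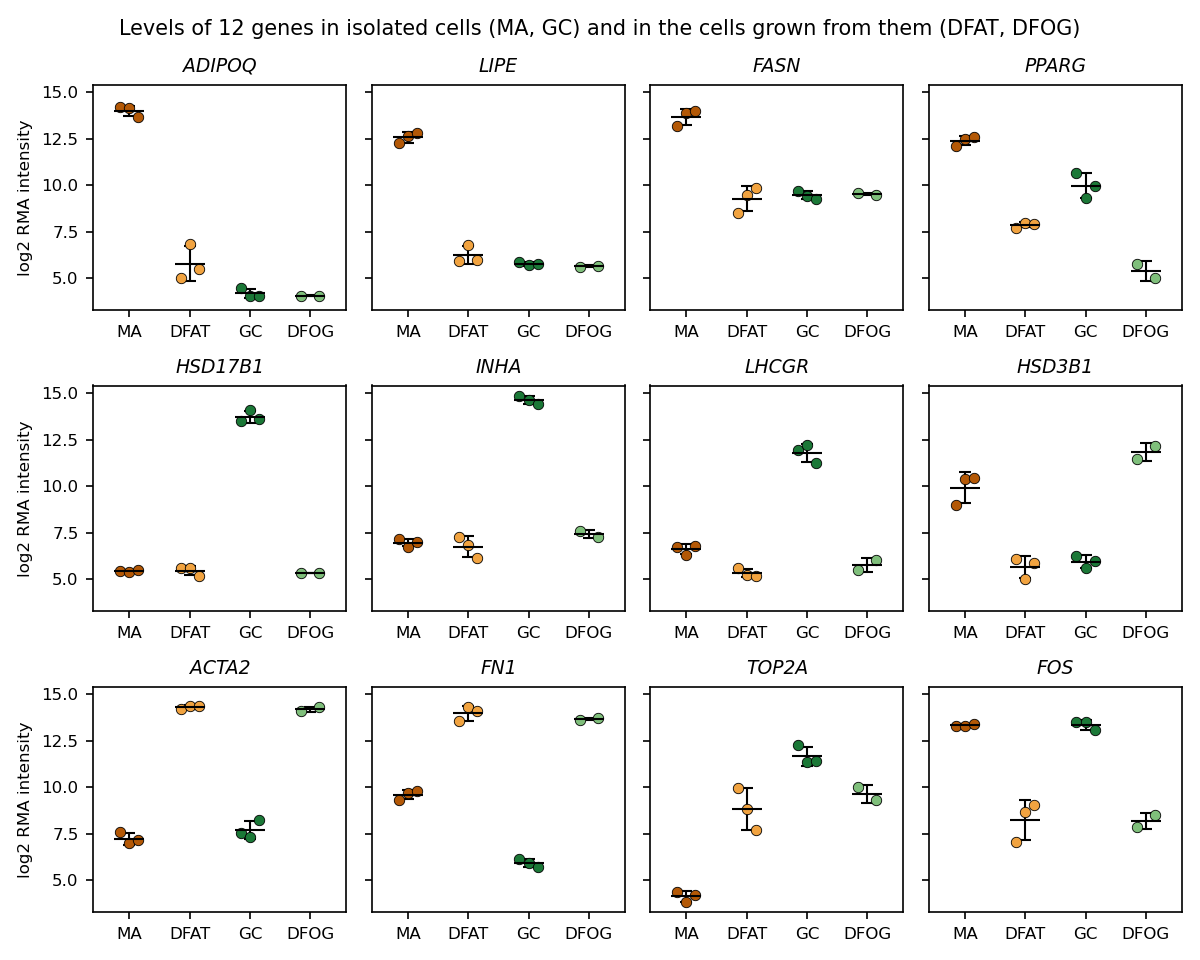
Log2 levels of 12 genes in the 4 groups; points are samples and bars the mean with its SD (n = 3, DFOG n = 2). ADIPOQ lay at 13.99 in MA and 5.78 in DFAT, HSD17B1 at 13.72 in GC and 5.32 in DFOG, and ACTA2 at 14.30 in DFAT and 14.18 in DFOG.

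Dedifferentiation of granulosa cells was examined by comparing DFOG (n = 2) with GC (n = 3). In the granulosa cell identity list 11 of 22 members fell and 1 rose, while 19 of 21 actin cytoskeleton and adhesion genes and 16 of 20 fibrillar matrix genes rose. HSD17B1, which makes oestradiol from oestrone, fell from 13.72 ± 0.33 to 5.32 ± 0.00 (SD), a log2 change of -8.40 ± 0.21 (SE, limma adjusted p = 1.73e-09). INHA, the alpha subunit of the hormone inhibin, changed from 14.64 ± 0.21 to 7.44 ± 0.22 (SD), by -7.20 ± 0.29 (SE, limma adjusted p = 3.30e-08). COL15A1, a collagen near basement membranes, rose by 8.56 ± 0.17 (SE, limma adjusted p = 2.60e-10), from 4.12 ± 0.14 to 12.68 ± 0.20 (SD). In all, 5971 probe sets changed, 2958 up and 3013 down, 4074 of them at least 2-fold, and of the named genes 1166 rose and 904 fell. With the actin 3′ to 5′ difference as a covariate 3790 of the 5971 kept their call.

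In the granulosa cell identity list 11 of 22 members fell and 1 rose, also when adjusted over the list alone, with a median of -0.86 (camera adjusted p = 2.51e-06, and adjusted p = 0.0826 with an estimated correlation). Besides HSD17B1 and INHA, the luteinising hormone receptor LHCGR changed by -6.02 ± 0.29, follistatin FST by -5.19, the nuclear receptor NR5A2 by -4.75, the activin subunit INHBB by -3.52, anti-Müllerian hormone AMH by -2.67 and SERPINE2 by -2.46. The member that rose was KITLG (0.71). The aromatase gene CYP19A1 (0.17) and FOXL2 (0.05) did not pass the test. In steroid hormone synthesis 8 of 15 members fell and 3 rose, also when adjusted over the list alone (median -0.92, camera adjusted p = 0.0108, and adjusted p = 0.265 with an estimated correlation). HSD17B1, NR5A2 and CYP19A1 stand on both lists, so the 2 camera results share genes. The electron carrier FDXR changed by -4.20, while HSD3B1, which makes progesterone from pregnenolone, rose by 5.88 ± 0.46, from 5.95 ± 0.33 to 11.82 ± 0.48 (SD). The steroid enzyme CYP11A1 lay at 8.73 ± 0.85 in GC and 11.03 ± 0.42 in DFOG (SD). The largest falls outside these lists were those of the glutathione transferase GSTA1 (-8.16 ± 0.19), DAPL1 (-8.15 ± 0.18), ACSL6 (-6.73), MAL2 (-6.02), the growth factor carrier IGFBP2 (-5.40 ± 1.20) and SELENBP1 (-5.40).

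The actin cytoskeleton and adhesion list had 19 of 21 members rise and none fall, also when adjusted over the list alone, with a median of 2.92 (camera adjusted p = 2.52e-14, and adjusted p = 0.119 with an estimated correlation). TAGLN rose by 7.71 ± 0.21, CNN1 by 7.07, ACTA2 by 6.49 and the actin crosslinker ACTN1 by 5.63, and outside the list FHL2 rose by 8.40 ± 0.24. In fibrillar matrix 16 of 20 rose and none fell, also when adjusted over the list alone (median 3.48, camera adjusted p = 4.43e-10, and adjusted p = 0.152 with an estimated correlation). FN1 rose by 7.74 ± 0.24, decorin DCN by 7.61 ± 0.53, the crosslinking enzyme LOX by 6.79 and lumican LUM by 6.10. Matrix proteolysis had 8 of 15 rise and none fall (9 when adjusted over the list alone; median 1.43, camera adjusted p = 0.00247, and adjusted p = 0.334 with an estimated correlation), among them MMP1 (4.29) and TIMP1 (3.13). The mesenchymal stromal cell surface list had 8 of 12 rise and none fall, also when adjusted over the list alone (median 1.27, camera adjusted p = 0.00143, and adjusted p = 0.358 with an estimated correlation), with VCAM1 at 6.27 ± 0.86, PDGFRB at 4.50 and THY1 at 4.35. The actin 3′ minus 5′ difference was 1.35 in GC and 0.39 in DFOG.

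Cytokines and chemokines had 7 of 16 members rise and none fall (8 when adjusted over the list alone), and their median was 0.62, or -0.17 with arrays centred on the poly-A controls. The list's camera adjusted p was 0.00360 (adjusted p = 0.472 with an estimated correlation). The monocyte attractant CCL2 rose by 8.33 ± 0.57, LIF by 5.48, IL18 by 5.26 and TGFB1 by 4.37. In mitosis 3 of 14 members fell and none rose (4 when adjusted over the list alone; median -0.97, camera adjusted p = 0.0108, and adjusted p = 0.728 with an estimated correlation), and TOP2A changed by -2.01. Theca cell and oocyte markers had 3 of 9 fall, also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0417, and adjusted p = 0.334 with an estimated correlation), LHCGR and the theca gene INSL3 (-3.01) among them, and LHCGR is also a granulosa gene. Camera no longer passed for steroid hormone synthesis with poly-A centring (adjusted p = 0.0610), for theca cell and oocyte markers in 6 settings, among them array weights (adjusted p = 0.0590) and fits without MA replicate 1 or DFAT replicate 1 or 2 (adjusted p = 0.0533, 0.0537 and 0.0519). Fry, which does not compare a list with other genes, did not pass for mitosis (adjusted p = 0.164).

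The remaining lists did not pass camera. DNA replication had none of 13 members past the test (adjusted p = 0.265). Basement membrane had 2 of 6 rise, LAMB1 by 7.16 and NID2 by 3.43, and LAMB2 fall (-2.38; adjusted p = 0.452). Osteogenic, chondrogenic and myogenic genes had 6 of 15 rise and 1 fall (adjusted p = 0.0713), with SPP1 at 5.47 and DLX5 at 4.96. Immediate early and heat shock genes had 6 of 14 fall and 2 rise (adjusted p = 0.0797), with FOS at -5.17, ATF3 at -3.27 and IER3 at 3.03. In pluripotency MYC rose by 3.01 while KLF4 changed by -3.01 (adjusted p = 0.629 for the list). Glycolysis had 7 of 16 rise and 2 fall (adjusted p = 0.125), SLC2A1 by 3.15 among them, and oxidative phosphorylation had 2 of 16 fall (adjusted p = 0.403). The adipocyte identity list had 2 of 14 rise and 1 fall (adjusted p = 0.886), the fall being that of PPARG (-4.60 ± 0.36). Fatty acid and triglyceride synthesis had 3 of 17 rise and 1 fall (adjusted p = 0.695), with ACSL1 at 3.95 and AGPAT2 at -3.07. Lipolysis and fatty acid oxidation had 3 of 18 rise and 2 fall (adjusted p = 0.918), and cholesterol synthesis 2 of 10 fall (adjusted p = 0.365). Ribosome, lymphocyte, erythrocyte and skeletal muscle lists had no member past the test. Macrophage markers had 1 of 13 rise (adjusted p = 0.857), endothelial markers 2 of 12 rise and 1 fall, TIE1 by -2.47 (adjusted p = 0.999), and epithelial and mesothelial markers 3 of 9 rise (adjusted p = 0.208), with the keratin KRT19 at 4.48 and desmoplakin DSP at 3.84. Adjusted over the list alone, the counts were the same for these lists except basement membrane (2 rose, 2 fell), immediate early genes (2 rose, 7 fell), glycolysis (8 rose, 3 fell), oxidative phosphorylation (1 fell), fatty acid and triglyceride synthesis (4 rose, 1 fell) and epithelial and mesothelial markers (3 rose, 1 fell). Camera passed for some of these lists in other settings. Glycolysis passed with reference genes (adjusted p = 0.0376), and DNA replication with the actin covariate (adjusted p = 0.0373). The osteogenic, chondrogenic and myogenic list passed without GC replicate 3 (adjusted p = 0.0408) and with the actin covariate (adjusted p = 0.0484). Immediate early genes passed with the replicate block (adjusted p = 0.0309) and without GC replicate 3 (adjusted p = 0.0218). With poly-A centring glycolysis (adjusted p = 0.0313), the osteogenic list (adjusted p = 0.0177) and epithelial and mesothelial markers (adjusted p = 0.0328) passed. This centring turned the medians of glycolysis, of the osteogenic list and of the epithelial list to -0.12, -0.56 and -0.47. Fry, with its different question, passed for 5 of the lists in this paragraph. Without DFOG replicate 1, 3586 probe sets changed, in a fit where the lone DFOG sample is assumed to vary like the others. The split of 2958 higher and 3013 lower became 2020 and 4841 with arrays centred on reference genes, and 1062 and 9355 on poly-A controls, which moved the median of all probe sets from -0.02 to -0.31 and to -0.81.

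**Figure D3:**
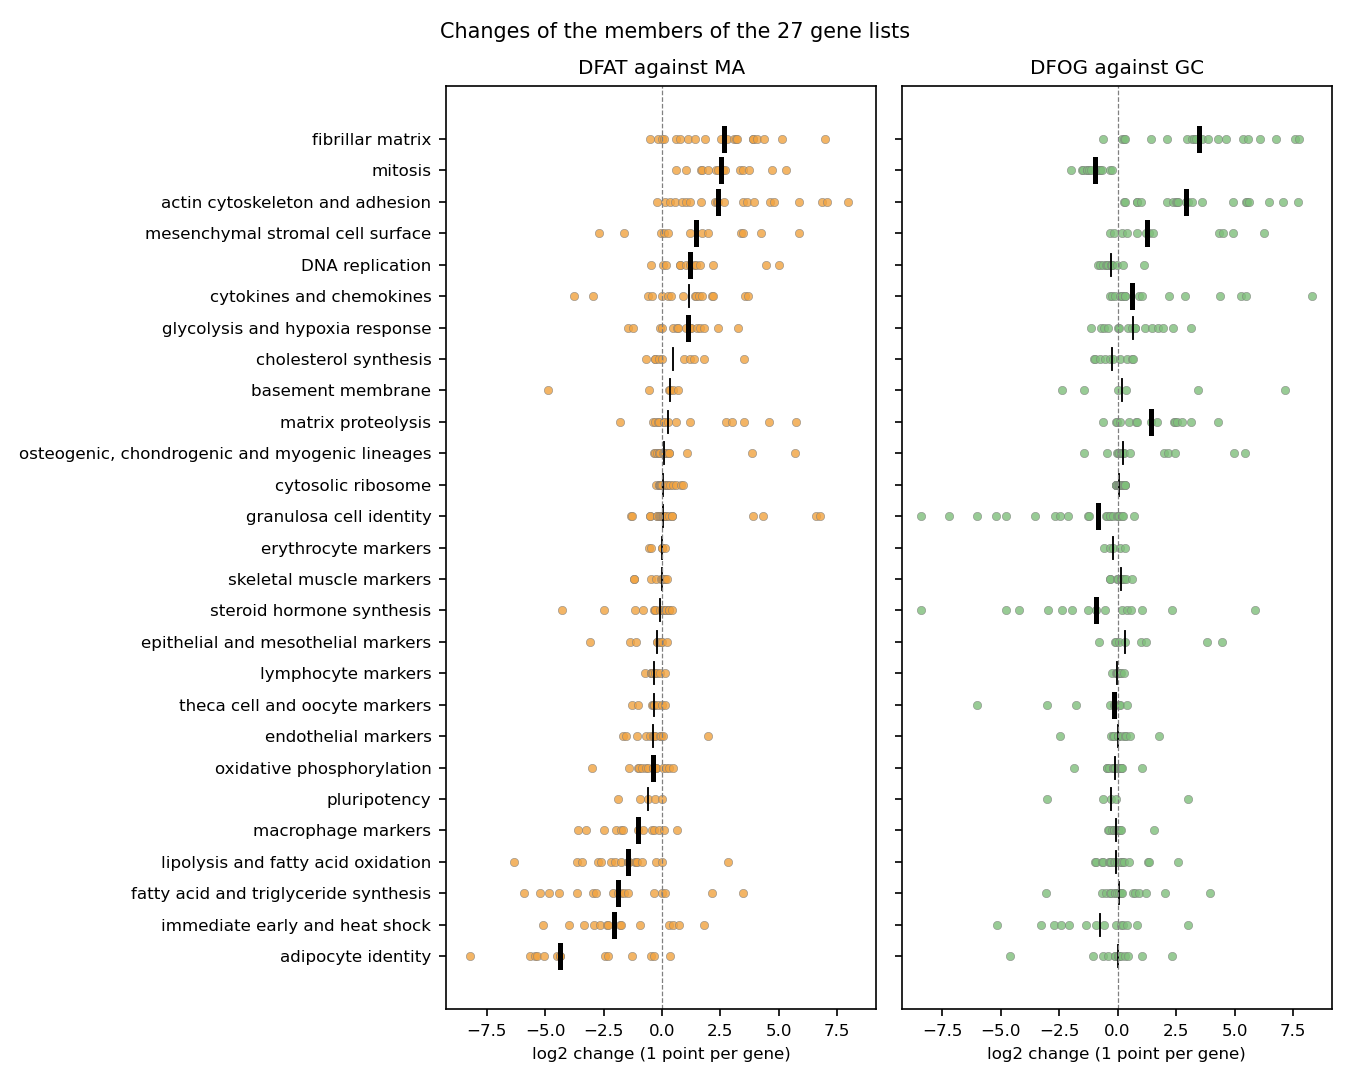
Log2 changes of the genes of each list in DFAT against MA and in DFOG against GC; points are genes and bars list medians, bold where the camera adjusted p was under 0.05. Adipocyte identity had a median of -4.37 in DFAT against MA, actin cytoskeleton and fibrillar matrix lists had medians of 2.41 to 3.48 in both, and with arrays centred on the poly-A controls the medians of oxidative phosphorylation in DFAT (-0.39) and of cytokines in DFOG (0.62) turned to 0.24 and -0.17, as did those of other lists near 0.

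The 2 dedifferentiations were then set side by side, in comparisons that share no samples. Ranked by the smaller of the 2 changes, FHL2 rose by 7.50 in DFAT and 8.40 in DFOG, CNN1 by 7.93 and 7.07, CDH11 by 7.41 and 6.65, ACTA2 by 7.07 and 6.49, ACTG2 from 4.31 to 14.31 and from 6.71 to 12.39, TMEM26 by 6.68 and 5.61, TPM2 by 6.85 and 5.51, and SPP1 by 5.71 and 5.47. FOS fell by 5.07 and 5.17, PDK4 by 7.25 and 4.97, CDO1 by 7.64 and 4.55 and PPARG by 4.51 and 4.60, and MAL2, CITED1, FGL2 and the glutathione transferase MGST1 also fell in both. In all, 2387 probe sets changed the same way, 1418 up and 969 down, where independent lists would share 464 and 495. The interaction passed for 659 of them, which therefore changed by different amounts. Across probe sets the changes had r = 0.325 and rho = 0.264, and 58.8% had the same sign, though probe sets are not independent replicates. With arrays centred on reference genes the common changes split into 995 up and 1553 down. Fewer probe sets changed the same way with the actin 3′ to 5′ difference as a covariate or with poly-A centring, as given below.

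Opposite changes were fewer than independent lists would share. A rise in DFAT with a fall in DFOG was found for 346 probe sets (473 for independent lists), and a fall in DFAT with a rise in DFOG for 376 (486 for independent lists). The first kind included IGFBP2 (5.24 and -5.40), which no longer passed in DFAT with the actin 3′ to 5′ difference as a covariate, the prostaglandin E synthase PTGES (3.39 and -3.25), RARRES1 (4.16 and -2.61), the lipoprotein receptor LRP8 (2.57 and -4.13), LHFPL2 (3.14 and -2.89) and MSANTD3 (2.64 and -3.26). The second included HSD3B1 (-4.27 and 5.88), ACSL1 (-2.84 and 3.95), the lipase co-activator ABHD5 (-2.59 and 2.57) and GPNMB (-3.06 and 2.99).

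The interaction, the change in DFAT against MA minus that in DFOG against GC, passed for 5593 probe sets, 2775 of them positive and 2818 negative. It was largest for IGFBP2 (10.64 ± 1.61), SERPINE2 (9.03 ± 0.38), HSD17B1 (8.43 ± 0.28), DAPL1 (7.98 ± 0.24), VCAN (7.95 ± 0.44) and GSTA1 (7.78 ± 0.26) on the positive side. On the negative side it was largest for HSD3B1 (-10.14 ± 0.61), CA3 (-8.64 ± 0.37), PON3 (-8.61 ± 0.49), ADIPOQ (-8.09 ± 0.56), COL15A1 (-7.96 ± 0.22) and VCAM1 (-7.90 ± 1.15). By its construction the interaction is also the difference of DFAT from DFOG minus that of MA from GC. A gene low in 1 starting cell type could fall little there, so large values partly restate the starting levels. The cell division lists changed differently, since mitosis genes rose in DFAT and not in DFOG. The interaction was positive for 12 of 14 mitosis genes and negative for none (13 when adjusted over the list alone; median 3.50, camera adjusted p = 1.39e-07, and adjusted p = 0.472 with an estimated correlation). TOP2A lay at 4.13 ± 0.27 in MA, 11.66 ± 0.51 in GC, 8.82 ± 1.14 in DFAT and 9.64 ± 0.48 in DFOG (SD). For the actin cytoskeleton and fibrillar matrix lists the interaction did not pass camera (adjusted p = 0.916 and 0.222), although it passed for 7 of 21 and 14 of 20 of their members. For fibrillar matrix camera passed with poly-A centring (adjusted p = 0.000340), which moved the median from -1.31 to 0.12. The limma test fry, which does not compare a list with other genes, gave it an adjusted p of 0.0193. The median of the actin cytoskeleton list was -0.10, and it turned to 0.10 with quantile normalization again, 0.08 with reference genes and 1.33 with poly-A centring, without passing. With arrays centred on the poly-A controls 16040 probe sets had a positive and 721 a negative interaction, since this moved the median of all probe sets to 1.37.

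**Figure D4:**
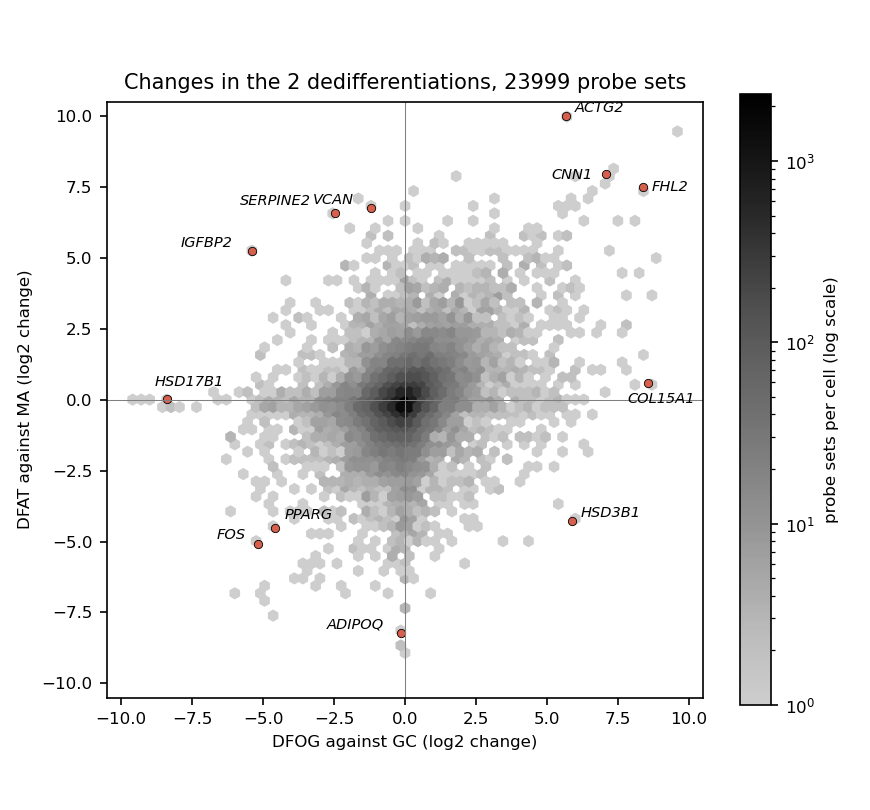
Log2 change of 23999 probe sets in DFOG against GC (horizontal) and in DFAT against MA (vertical), shaded by the number of probe sets per cell on a log scale. FHL2 (8.40, 7.50) and CNN1 (7.07, 7.93) lie at upper right, FOS and PPARG at lower left, HSD3B1 (5.88, -4.27) and IGFBP2 (-5.40, 5.24) in the opposite corners, and ADIPOQ and HSD17B1 along 1 axis each.

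The 2 starting cell types were compared directly (n = 3 each). FABP4, a fatty acid carrier of adipocytes, was higher in MA than in GC by 10.76 ± 0.36 (limma adjusted p = 3.49e-09), followed by ADIPOQ (9.80), angiotensinogen AGT (9.59), caveolin CAV1 (8.92), CA3 (8.84) and PON3 (8.68). RARRES1 was lower, at 4.04 ± 0.09 in MA and 13.04 ± 0.25 in GC (SD, limma adjusted p = 3.49e-09), followed by SERPINE2 (-8.93), PRR15 (-8.76), LRP8 (-8.47), NR5A2 (-8.37) and DAPL1 (-8.32). The comparison had 9713 changed probe sets, 4976 higher and 4737 lower in MA, and with arrays centred on poly-A controls 1146 higher and 19065 lower, where the median of all probe sets moved from 0.07 to -1.27 and 702 of the 9713 were called in the other direction.

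Adjusted over the list alone, the counts of the lists that follow were the same except for fibrillar matrix. Adipocyte identity was higher in MA for 12 of 14 members and lower for none, with a median of 4.92 (camera adjusted p = 5.38e-07, and adjusted p = 0.0610 with an estimated correlation). Lipolysis and fatty acid oxidation was higher for 14 of 18 and lower for 2 (median 1.48, camera adjusted p = 0.000255, and adjusted p = 0.0610 with an estimated correlation), and fatty acid and triglyceride synthesis for 11 of 17 and lower for 3 (median 2.02, camera adjusted p = 0.00448, and adjusted p = 0.417 with an estimated correlation). Granulosa identity was lower for 14 of 22 and higher for 2 (median -3.50, camera adjusted p = 1.88e-07, and adjusted p = 0.0610 with an estimated correlation). All 14 mitosis genes were lower in MA (median -4.37, camera adjusted p = 6.80e-08, and adjusted p = 0.470 with an estimated correlation), as were 11 of 13 DNA replication genes (median -1.93, camera adjusted p = 8.54e-06, and adjusted p = 0.478 with an estimated correlation). Fibrillar matrix was higher in MA for 12 of 20 and lower for 3 (15 and 3 when adjusted over the list alone; median 2.20, camera adjusted p = 0.00143, and adjusted p = 0.478 with an estimated correlation). Macrophage markers were higher in MA for 10 of 13 (median 1.44, camera adjusted p = 0.00143, and adjusted p = 0.533 with an estimated correlation). Cytokines and chemokines were higher for 7 of 16, with a median of 0.82, or -0.53 with arrays centred on the poly-A controls (camera adjusted p = 0.0142, and adjusted p = 0.533 with an estimated correlation), and no longer passed with the dimmest probe sets left out (adjusted p = 0.0510).

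Between the 2 cultures fewer probe sets differed. DFAT (n = 3) and DFOG (n = 2) differed in 1921 probe sets, 887 higher and 1034 lower in DFAT. The small leucine-rich proteoglycan ASPN was higher in DFAT by 8.04 ± 0.30 (limma adjusted p = 8.13e-08), followed by the collagen COL6A3 (6.75 ± 0.59), SERPINF1 (5.95), the homeobox gene HOXA9 (5.60) and the complement proteases C1S (5.27) and C1R (5.22). Monoamine oxidase MAOB was lower by -7.20 ± 0.24 (limma adjusted p = 6.11e-08), followed by PERP (-6.72), RGS5 (-6.61), the steroid enzymes CYP11A1 (-6.59) and HSD3B1 (-6.17), and PRR15 (-5.89). CYP11A1, which makes pregnenolone from cholesterol, lay at 11.03 ± 0.42 in DFOG and 4.44 ± 0.39 in DFAT (SD).

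Some genes of each origin still differed between the cultures. Adipocyte identity was higher in DFAT for 7 of 14 members and lower for none (10 when adjusted over the list alone; median 1.22, camera adjusted p = 1.89e-06, and adjusted p = 0.0610 with an estimated correlation), including FABP4 (4.07), PCK1 (3.23), PPARG (2.50), CIDEA (2.07) and ADIPOQ (1.72). Granulosa identity was lower in DFAT for 4 of 22 (6 when adjusted over the list alone; median -0.10, camera adjusted p = 0.00585, and adjusted p = 0.329 with an estimated correlation), namely GATA4 (-4.21), NR5A2 (-3.18), BMPR1B (-3.04) and the follicle-stimulating hormone receptor FSHR (-2.30). Cholesterol synthesis was higher in DFAT for 5 of 10 (8 when adjusted over the list alone; median 1.04, camera adjusted p = 1.27e-05, and adjusted p = 0.334 with an estimated correlation), and fibrillar matrix for 10 of 20 (10 higher and 2 lower when adjusted over the list alone; median 0.87, camera adjusted p = 0.000102, and adjusted p = 0.377 with an estimated correlation). Epithelial and mesothelial markers were lower in DFAT for 2 of 9 (4 when adjusted over the list alone; median -0.46, camera adjusted p = 0.00166, and adjusted p = 0.186 with an estimated correlation), namely KRT19 (-4.25) and DSP (-4.23). Steroid hormone synthesis was lower for 4 of 15 and higher for 1, with a median of -0.07, or 0.0056 with arrays centred on the poly-A controls (camera adjusted p = 0.0420, and adjusted p = 0.334 with an estimated correlation). Mitosis had a median of -0.63 with none of 14 members past the test (camera adjusted p = 0.0267, and adjusted p = 0.777 with an estimated correlation). Macrophage markers did not pass (median -0.03, or 0.05 with arrays centred on the poly-A controls, camera adjusted p = 0.699). Mitosis no longer passed camera without DFOG replicate 1 (adjusted p = 0.189) or DFAT replicate 2 or 3 (adjusted p = 0.0728 and 0.488), and steroid hormone synthesis without DFOG replicate 1 or DFAT replicate 1 or 3 (adjusted p = 0.0508, 0.0582 and 0.0877), its median being 0.07 without DFOG replicate 1. Without DFOG replicate 1, 1103 probe sets differed, and in a fit on the arrays of these 2 groups alone 1025 did.

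The distance between the lineages was described by the correlation of arrays over all tested probe sets, which are not independent, and no test was made. The mean r of MA with GC was 0.824 (0.821 to 0.828 over 9 pairs) and that of DFAT with DFOG was 0.943 (at least 0.938 over 6 pairs), while pairs within a group had 0.981 (0.968 to 0.992). DFAT with MA had 0.878 and DFOG with GC 0.892. Over the 4 groups together, 12177 probe sets passed limma's F-test, and more passed with arrays centred on the poly-A controls, as given below.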

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

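The tests of the macrophage pattern were chosen after the result was seen, and the split of the markers by their level in MA after the first of these tests.

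The change with dedifferentiation differed between the 2 cell types, by limma's interaction test, for the genes and lists that follow, given as the change in DFAT against MA minus the change in DFOG against GC on the log2 scale. The difference was 10.64 for IGFBP2, 9.03 for SERPINE2, 8.43 for HSD17B1, 7.98 for DAPL1, 7.95 for VCAN and 7.78 for GSTA1. It was -10.14 for HSD3B1, -8.64 for CA3, -8.61 for PON3, -8.09 for ADIPOQ, -7.96 for COL15A1 and -7.90 for VCAM1. IGFBP2 had the widest spread of these, at 10.90 ± 2.91 (SD, n = 3) in DFAT. Several of these differences follow from the starting levels. ADIPOQ, CA3 and PON3 were low in GC (4.19, 3.95 and 3.30) and could fall little there. HSD17B1, DAPL1 and GSTA1 were already low in MA (5.43, 4.76 and 6.17). SERPINE2 ended at 11.53 in DFAT and 11.43 in DFOG and VCAN at 10.96 and 11.04, so their values mostly restate the difference between MA and GC. The identity lists also carry that difference.

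Among the lists, the median difference was 2.37 for granulosa identity, with 12 of 22 members positive and 1 negative (13 and 1 when adjusted over the list alone, camera adjusted p = 1.39e-07, and adjusted p = 0.0610 with an estimated correlation). It was -3.42 for adipocyte identity, with 8 of 14 negative (9 when adjusted over the list alone, camera adjusted p = 9.32e-06, and adjusted p = 0.0610 with an estimated correlation), and -1.90 for fatty acid and triglyceride synthesis (camera adjusted p = 0.000383, and adjusted p = 0.322 with an estimated correlation). For lipolysis and fatty acid oxidation it was -1.39, or 0.03 with arrays centred on the poly-A controls (camera adjusted p = 5.99e-05, and adjusted p = 0.0610 with an estimated correlation). For mitosis it was 3.50 (camera adjusted p = 1.39e-07, and adjusted p = 0.472 with an estimated correlation) and for DNA replication 1.68 (camera adjusted p = 0.000102, and adjusted p = 0.533 with an estimated correlation). For cholesterol synthesis it was 0.70 (camera adjusted p = 0.0264, and adjusted p = 0.592 with an estimated correlation), and it no longer passed without DFOG replicate 1 (adjusted p = 0.0693) or DFAT replicate 2 (adjusted p = 0.0532), with poly-A centring (adjusted p = 0.112) or with the mean over a gene's probe sets (adjusted p = 0.0717). For epithelial and mesothelial markers it was -1.24, or 0.18 with arrays centred on the poly-A controls (camera adjusted p = 0.0131, and adjusted p = 0.313 with an estimated correlation). For macrophage markers it was -1.60, with 7 of 13 negative, also when adjusted over the list alone (camera adjusted p = 0.00685, and adjusted p = 0.555 with an estimated correlation).

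The macrophage pattern may come from macrophages carried along with the isolated adipocytes and lost in culture. The markers were higher in MA than in GC by a median of 1.44, which that explanation needs, with CD74 at 7.63 ± 0.12 and C1QC at 7.08 ± 2.04 (SD, n = 3) in MA against 4.91 ± 0.15 and 3.51 ± 0.09 in GC. C1QC was lower in MA 1 (4.74) than in MA 2 and MA 3 (8.12 and 8.40). CD74 lay at 7.56, 7.57 and 7.77 in these samples, so the 2 genes did not vary together. A loss of all blood and vessel cells alike stays open: the macrophage median in DFAT against MA lay -0.67 from that of endothelial and lymphocyte markers (permutation p = 0.0132), but 14 of those 22 markers lay under 5.27 in MA, near the floor, and cannot fall far. With markers above that level alone the difference was -1.39 (permutation p = 0.0256), but EGFL7 was as high in GC (8.12) as in MA (8.26) and ENG rose by 1.99, so neither singles out vessel cells here, while PECAM1 (-1.65), CLDN5 (-1.55) and ESAM (-0.70) fell. Both permutations were over marker genes, which are not independent, so their p-values do not measure the spread between samples. None of the macrophage markers stands on another list, but CD14 was as high in DFOG (6.74 ± 0.31) as in MA (6.63 ± 0.34), so it does not single out macrophages here, and expression of the macrophage markers by the adipocytes themselves was not tested.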

How the results depend on the processing

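The 12 arrays as separate samples, the actin covariate and the poly-A centring were chosen after the data were seen. Of 4577 values of named genes and lists under settings other than leaving out an array, 4366 stayed on their side of the threshold, 147 no longer passed (46 of them lists under an estimated correlation), 60 newly passed (41 of them lists under fry, which asks another question than camera) and 4 reversed. The named genes were chosen for large changes past the test in these samples, so most were likely to stay. These counts do not measure how stable the other calls are. For lists a reversal was counted by the test's direction with a passing test, not by the sign of the median. List medians turned sign more often, also with quantile normalization again, median centring and reference genes. That of adipocyte identity in DFOG against GC went from 0.008 to -0.28 with reference genes. The 4 counted reversals came from poly-A centring, which shifts all changes of a comparison by 1 amount: MYC 0.025, CD8A 0.15 and ALAS2 0.14 in DFAT against MA, and EGFL7 -0.26 in DFOG against GC. That centring also gave 10417 probe sets for DFOG against GC, 16761 for the interaction, 20211 for MA against GC, 1460 changed the same way and 20562 in the F-test. The 2-fold minimum left 4781 for DFAT against MA, 6165 for MA against GC and 1422 changed the same way, by its construction. With the actin covariate 1556 changed the same way, and 4301 of 7706 and 3790 of 5971 calls were kept in DFAT against MA and DFOG against GC. The covariate was on average 1.09 higher in isolated than in cultured cells, so lost precision and RNA quality are not told apart here. A fit on the 2 cultures alone gave 1025 for DFAT against DFOG; the cause was not tested. The mean r of MA with GC was 0.838 by Spearman's method. Without the dimmest probe sets it was 0.627, and that of DFAT with DFOG was 0.882.

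With each array left out in turn the counts ranged from 6429 to 7979 for DFAT against MA, 3586 to 6563 for DFOG against GC, 4130 to 5899 for the interaction, 8373 to 10168 for MA against GC, 1103 to 2138 for DFAT against DFOG, 1593 to 2469 changed the same way and 10840 to 12358 in the F-test. The lowest for DFOG against GC and for DFAT against DFOG came without DFOG replicate 1, which leaves 1 DFOG sample, assumed to vary like the others. Mean r stayed between 0.823 and 0.825 for MA with GC and between 0.942 and 0.945 for DFAT with DFOG. Of the values of named genes and lists 4650 stayed on their side of the threshold, 100 no longer passed and 14 newly passed. The choice of named genes for large changes limits this count too.

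The labels give each group the numbers 1 to 3. Deviations of MA and DFAT samples with the same number had r = 0.0999, 0.168 and 0.126, so not every pair was over 0.1, the limit set for pairing, and the numbers were not used to pair samples. Each MA sample correlated best with its own number, a hint from the data, and the labels do not say whether the numbers pair them, so this stays open. DFOG had too few separate samples for this check. With the replicate block 8426 probe sets changed in DFAT against MA, 5844 in DFOG against GC, 5719 in the interaction, 10017 in MA against GC, 1922 in DFAT against DFOG and 2487 the same way. The 12 arrays as separate samples gave 8294, 7322, 6639, 10301, 2757 and 2862 in that order. Changes near the floor of the arrays are understated, since no signal over background was given.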

Other observations

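The 12 lists of the next paragraphs, and the tests of stromal takeover and of the near-identical arrays, were chosen after the results were seen.

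In a list of genes that break down branched-chain amino acids most members fell in both dedifferentiations. In DFAT against MA 12 of 16 members fell and 2 rose (13 and 2 when adjusted over the list alone), with a median of -1.94 (camera adjusted p = 0.000115, and adjusted p = 0.306 with an estimated correlation), and in DFOG against GC 11 fell and 1 rose, also when adjusted over the list alone (median -0.77, camera adjusted p = 0.00599, and adjusted p = 0.439 with an estimated correlation). The interaction was negative for 9 of 16 and positive for none (9 and 1 when adjusted over the list alone). Its median was -0.99, or 0.43 with arrays centred on the poly-A controls (camera adjusted p = 0.0328, and adjusted p = 0.508 with an estimated correlation). BCKDHB, a subunit of the dehydrogenase that commits these amino acids to breakdown, changed by -3.41 in DFAT and -2.24 in DFOG and AUH by -2.79 and -1.57, while BCAT1, the cytosolic aminotransferase, rose by 3.45 and 2.91. Genes of protein folding and transport in the endoplasmic reticulum rose for 13 of 29 members in DFAT, with 1 fall (14 and 1 when adjusted over the list alone; median 0.60, camera adjusted p = 0.00363, and adjusted p = 0.763 with an estimated correlation), and for 11 of 29 in DFOG, also when adjusted over the list alone (median 0.45, or -0.34 with arrays centred on the poly-A controls, camera adjusted p = 0.00643, and adjusted p = 0.785 with an estimated correlation). The coat protein SEC24D rose by 2.63 and 3.01 and the retrieval receptor KDELR3 by 1.96 and 2.99. TGF-beta and BMP pathway genes rose for 9 of 18 in DFAT (10 when adjusted over the list alone; median 0.85, camera adjusted p = 0.0281, and adjusted p = 0.439 with an estimated correlation), and for 6 with 2 falls in DFOG (7 and 2 when adjusted over the list alone), where camera did not pass (adjusted p = 0.0772).

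A list of 8 homeobox genes and WT1 was compared between the lineages. It was higher in MA than in GC for 8 of 9 members (8 higher and 1 lower when adjusted over the list alone; median 2.14, camera adjusted p = 0.00363, and adjusted p = 0.215 with an estimated correlation) and in DFAT than in DFOG for 4 of 9 (7 higher and 1 lower when adjusted over the list alone; median 0.75, camera adjusted p = 0.000115, and adjusted p = 0.130 with an estimated correlation). WT1 lay on the other side in both, at -1.30 and -2.07, without passing over all probe sets. HOXA9 lay at 9.34 ± 0.13 in MA, 9.15 ± 0.43 in DFAT (SD, n = 3), 3.17 ± 0.14 in GC (n = 3) and 3.54 ± 0.08 in DFOG (n = 2). Interferon response genes were higher in DFAT than in DFOG for 5 of 20 (13 when adjusted over the list alone; median 1.26, camera adjusted p = 3.92e-05, and adjusted p = 0.508 with an estimated correlation), ISG15 by 2.93. Some interferon genes varied widely between samples of a group. Their SE in DFOG against GC was 1.34 for OAS1 and 0.81 for ISG15, against 0.18 for B2M. Complement genes were higher for 4 of 19 (8 when adjusted over the list alone; median 0.49, camera adjusted p = 0.00643, and adjusted p = 0.508 with an estimated correlation). In DFAT against MA 9 of the 12 lists did not pass camera. Glutathione and antioxidant genes had 15 of 29 fall and 4 rise (adjusted p = 0.0577), the IGF axis 6 of 11 rise and 1 fall (adjusted p = 0.0756) and the TCA cycle 11 of 22 fall and 3 rise (adjusted p = 0.0756). Interferon response genes had 6 of 20 rise and 3 fall (adjusted p = 0.310), complement genes 1 of 19 rise and 7 fall (adjusted p = 0.310), and the homeobox list 4 of 9 fall (adjusted p = 0.213). Wnt genes had 4 of 12 rise and 2 fall (adjusted p = 0.663), Notch genes 3 of 7 rise (adjusted p = 0.308), and the proteasome 5 of 26 rise and 4 fall (adjusted p = 0.968). Adjusted over the list alone these counts were the same, except that 5 glutathione genes and 7 interferon genes rose and 1 Notch gene fell. With arrays centred on the poly-A controls the medians of the TCA cycle, complement and homeobox lists turned from -0.54, -0.38 and -0.54 to 0.10, 0.25 and 0.09. In DFOG against GC the glutathione list had 10 of 29 fall and 5 rise (11 and 7 when adjusted over the list alone), and did not pass (adjusted p = 0.0772).

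The rise of fibrillar matrix and actin cytoskeleton genes in both dedifferentiations may be biological, and 3 other explanations were tested. A difference in RNA integrity stays open. With the actin 3′ to 5′ difference as a covariate the lowest of the 4 list medians was 2.48, and at least 78.6% of the called members kept their call. The rise thus remained with this covariate. But the covariate is read from actin alone, actin genes are among those tested, and it was higher in isolated than in cultured cells. It may measure RNA integrity only in part, so the test does not decide. Scaling between arrays is argued against, since the lowest of the 4 list medians over 4 scalings was 2.13. Stromal cells taking over the cultures stay open: 11 members of the lists of origin were called higher in the culture of that origin, 7 of them adipocyte genes, but a mixture of cells from both sources would show this too. Other effects of growing in culture, as against isolated cells, coincide with dedifferentiation in both comparisons and were not tested. The design has no group that parts the explanations, so the biological one remains a hypothesis.

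A hypothesis of residual lineage identity was tested against gene sets that differed as much between MA and GC. Of 12 adipocyte identity genes that differed between MA and GC, 58.3% were called higher in DFAT than in DFOG, where matched sets had a median of 33.3% and a 95th percentile of 58.3% (permutation p = 0.0520), so this test does not decide. Of 14 granulosa genes 28.6% were called higher in DFOG, the same as the matched median of 28.6% (permutation p = 0.690), so the test gave no sign that granulosa genes keep their difference more often than other genes.

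For DFOG replicates 2 and 3, the hybridisation and poly-A controls also nearly coincided. The SD of their differences was 0.0540 over 63 control probe sets, against at least 0.190 in the other pairs of a group, which is consistent with 1 hybridised array entered under 2 names. The values are not identical, since 10.4% of probe sets differed by more than 0.1, and 1 labelled preparation put on 2 arrays would agree in the controls too, so this stays open.

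Other splits of the samples were counted for 3 results. The real split of the 6 MA and DFAT arrays gave 7706 probe sets and the highest of the other splits gave 6, and the real split of MA and GC gave 9713 and the highest other 0; only 1 of 10 splits reached the real count in each, and 10 splits are too few for a share under 0.05. For the F-test over the 4 groups, the real grouping gave 12177 probe sets and the highest of the other splits 3520. Of 100 splits only the real one reached its count, the lowest share that 100 splits can give. This argues against an arbitrary grouping. The labels do not say which animals or cultures the replicates came from, so chance is not excluded.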
